A study of Homo sapiens with 4 samples.

How the data were processed

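MicroRNAs were measured by real-time quantitative PCR in 4 samples of human adipose-derived stem cells, mesenchymal stromal cells of fat tissue, at passage 4. Per the labels' protocols, 2 samples held small RNA from microvesicles, the membrane vesicles that cells release into their medium. The vesicles came from medium of cells that had spent 4 days in an endothelial differentiation medium and then 2 days in a basal medium with 1% serum described as free of microvesicles. The other 2 samples were the cells themselves. Their labels name the same differentiation medium with 50 ng/ml VEGF for 4 days, but also a growth medium that keeps the cells undifferentiated, so whether the cell samples were preconditioned is left open here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

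The deposited values are raw threshold cycles (Ct), not normalised, per the file headers. The Ct is the PCR cycle at which the product becomes detectable, so a higher Ct means less template and 1 cycle is at most a 2-fold difference in template. A value of 40 stands where no crossing was recorded. Each sample held 768 assays on 2 cards of 384. Of these, 754 were microRNA assays, 12 were wells of the reference small RNAs U6, RNU44 and RNU48, and 2 were wells of a plant control. The 4 U6 wells of card 1 held 1 repeated value in each sample. The instrument, the threshold setting, the RNA input and any preamplification are not given in the sources used here, and unequal RNA input would shift all Ct values of a sample together. No genome build was needed. A gene table of assembly GRCh38.p14 served only to find which microRNA genes neighbour each other.

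A microRNA was called detected at a Ct under 35. The mean Ct over the 100 microRNAs detected in all 4 samples was subtracted from each sample and the sign was turned, which gave a relative level on a log2 scale that assumes doubling in each cycle. Relative levels were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates) over these 100 microRNAs, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. A change is given as microvesicles minus cells, with its standard error (SE). MicroRNAs detected in both samples of 1 group and in neither of the other have a fold that is a lower bound. It was computed with the undetected samples at the cutoff of 35 after the same centring. It holds as a bound only if a missing reading means little template. Because of this design a microRNA at the mean offset of both microvesicle samples passes the cutoff there only if its cell Ct is under 29.1. A microRNA later than this in cells could be tested only if it was relatively higher in microvesicles. The test needs detection in each sample, so the limit was earlier for microvesicles 1, whose Ct values were later.

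The 17 lists of microRNAs were fixed before the data were examined, as were the comparisons, the tests, the alternatives not described as added and the rule for naming microRNAs. Lists with at least 3 tested members were compared with the other tested microRNAs by limma's camera with its preset correlation of 0.01. Names that 2 assays shared (10 names) were left out of the lists. The panel marks the minor strand of a hairpin with #, which was taken as the older asterisk. The balance between the 2 arms of a hairpin was tested with limma on the difference between the arms. The text names the microRNAs past the threshold with the largest changes (where fewer than 5 passed in a direction, the 10 with the largest change whose groups did not overlap), the 10 with the lowest mean Ct in each group, the 8 with the lowest mean Ct detected in 1 group only, up to 4 of each list with the lowest mean Ct, the hairpins with the largest arm change, miR-31, miR-126, miR-210, miR-21 and miR-16, and all reference RNAs.

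Alternatives were no centring, centring on the median, on U6 or on miR-16, quantile normalisation, cutoffs of 32, 38 and none, undetected values set to the cutoff, the replicate number as a block, a variance trend, other list tests and leaving out each sample in turn. Added after the data were seen were leaving out assays with a Ct under 15, centring each card separately and rounding every Ct up. The test was checked on 100 simulated data sets of 100 microRNAs with the replicate spread of microvesicles against cells. It recovered 38.1% of changes of 2 on the log2 scale, 97.3% of those of 4 and 100% of those of 6, and 4.68% of its calls were false. The simulation gave all microRNAs of a group the same spread and applied no Ct cutoff. Its rates therefore do not measure the power or the false calls of the test on these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.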

Results

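The panel was read in 2 microvesicle samples and 2 samples of adipose-derived stem cells. Of 754 microRNA assays, 107 were detected in microvesicles 1 (14.2%, exact 95% interval 11.8 to 16.9%) and 193 in microvesicles 2 (25.6%, 22.5 to 28.9%). In the cells, 276 were detected in replicate 1 (36.6%, 33.2 to 40.2%) and 352 in replicate 2 (46.7%, 43.1 to 50.3%). The intervals treat assays as draws and do not cover differences in RNA input. The mean Ct of the 100 microRNAs detected in all samples was 30.1 ± 2.12 cycles in microvesicles (SD, n = 2) and 24.1 ± 1.61 in cells (SD, n = 2), a difference of 5.94 cycles. The replicates themselves lay apart by 3.00 cycles in microvesicles and 2.28 in cells. With 2 samples against 2, an exact two-sided test cannot go below p = 0.333. At a cutoff of 32, 53 and 128 microRNAs were detected in the microvesicle samples.

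Detection in microvesicles was compared with the Ct in cells, although Ct values of different assays do not rank microRNAs by amount. The lowest mean Ct in cells, leaving aside miR-1262, belonged to miR-222 (18.2 ± 1.75, SD, n = 2), miR-99a (18.8 ± 1.79), miR-100 (18.9 ± 1.49), let-7e (18.96 ± 1.82), miR-31 (19.2 ± 1.77), miR-221 (19.4 ± 1.82), miR-1274B (19.5 ± 2.07), miR-24 (19.7 ± 1.81) and miR-19b (19.8 ± 1.21). In microvesicles, miR-1274B (24.3 ± 2.46), miR-222 (25.1 ± 2.56), miR-1274A (25.1 ± 2.59), miR-1267 (25.8 ± 2.60), miR-99a (25.9 ± 2.86), miR-100 (26.02 ± 2.74), miR-720 (26.4 ± 3.62) and miR-17 (26.4 ± 2.19) came first after miR-1262 and miR-549. miR-1262 stood at a Ct of 9.60 ± 0.39 in microvesicles and 9.38 ± 0.22 in cells, about the same in every sample while other microRNAs moved by several cycles, and miR-549 was at 13.0 and 12.1 in microvesicles, 12.4 in cells 1 and 40 in cells 2. Among microRNAs detected in both cell samples, 50 of 56 (89.3%) with a mean cell Ct under 24 were detected in both microvesicle samples, against 11 of 114 (9.65%) with a mean cell Ct of 28 to 35 (two-sided Fisher exact test across microRNAs, p = 2.14e-25, where microRNAs are not independent replicates). Group means correlated across 99 microRNAs with Pearson's r of 0.761 and Spearman's rho of 0.852, leaving out the assay with a Ct under 15. The SD of the difference between replicates across the 100 microRNAs was 1.30 cycles in microvesicles and 0.746 in cells.

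**Figure D1:**
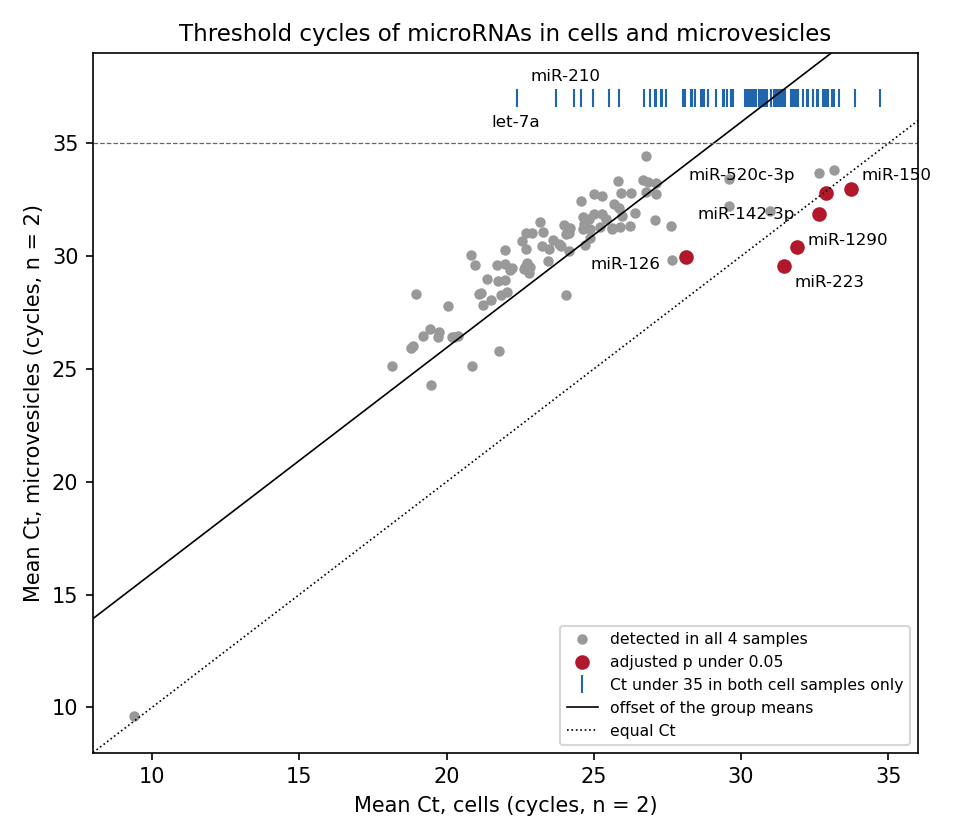
Mean Ct of each microRNA in cells (x axis, cycles, n = 2) against microvesicles (y axis, cycles, n = 2). Grey points are tested microRNAs, red points the 6 past the adjusted threshold, and blue ticks, drawn above the cutoff of 35 at no measured height, the 88 detected in both cell samples only; the solid line marks the offset of 5.94 cycles and the dotted line equal Ct, with 5 of the red points on its lower side and miR-126 above it.

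Relative levels were compared between microvesicles and cells. Only the microvesicle labels name 2 days in a basal medium with 1% serum. A difference in culture therefore cannot be separated from one between vesicles and the cells that released them. Relative to the mean of the common microRNAs, 6 of 100 were higher in microvesicles and 0 were lower (limma, adjusted p under 0.05). miR-223, a microRNA of myeloid cells, was higher by 7.84 on the log2 scale (SE 1.05, 229-fold, adjusted p = 0.0219), miR-142-3p, found in blood cells, by 6.72 (SE 0.44, 105-fold, adjusted p = 0.00417) and miR-150, a lymphocyte microRNA, by 6.67 (SE 0.91, 102-fold, adjusted p = 0.0219). miR-126, which is abundant in endothelial cells, was higher by 4.09 (SE 0.42, 17.1-fold, adjusted p = 0.0125). miR-1290 was higher by 7.44 (SE 0.80, adjusted p = 0.0125) and miR-520c-3p, of the primate chromosome 19 cluster, by 6.02 (SE 0.95, adjusted p = 0.0336). Both were on card 2, where centring each card separately lowered changes, as for miR-1274B from 1.12 to -1.34. All 6 calls were kept with that centring. Each of the 6 was higher in both microvesicle samples than in both cell samples. The raw Ct of miR-126 was later in microvesicles (29.98 ± 1.68) than in cells (28.1 ± 1.61), so that its level was higher only in relation to other microRNAs, and uncentred its change was -1.84. The mean raw Ct of the other 5 was earlier in microvesicles by only 0.08 (miR-520c-3p) to 1.90 cycles (miR-223). This is less than the 3.00 and 2.28 cycles between replicates, and the centring added 5.94 to every change. Of the 6, 5 had a mean cell Ct later than 29.1, where a microRNA could enter the test only if it was relatively higher in microvesicles. All 10 tested microRNAs in that range had a positive change. The limit of 29.1 averages both microvesicle samples and was earlier for microvesicles 1, where the common microRNAs had a mean Ct of 31.6. miR-126 had a mean cell Ct of 28.1. Of 38 microRNAs in both cell samples at a cell Ct of 28 to 30, 3 were detected in microvesicles 1. Selection by the cutoff thus stays open for miR-126 as well. Without microvesicles replicate 1 all 6 were among 18 higher microRNAs, and without microvesicles replicate 2 among 15. The 6 calls were lost without cells replicate 1 and without cells replicate 2 (0 calls in each). Their changes of 4.09 to 7.84 were then 4.00 to 8.38 and 4.05 to 9.19, while the spread came from the microvesicle replicates alone and the median SE of all tested microRNAs went from 0.476 to 0.581 and 0.664. Centring on U6 also left 0, although it adds 6.60 to every change. Relative to the microRNA mean, U6 differed by 9.03 cycles between the microvesicle replicates. Setting undetected values to the cutoff left 0 as well. Uncentred, 0 were higher and 85 lower, against 4 and 1 with quantile normalisation and 6 and 4 with each card centred separately. Centred on miR-16 they were 14 and 0, and with the replicate number as a block 16 and 12. The higher microRNAs in both, as with the median or with Ct rounded up, include miR-1262. Its change of 5.72 (SE 1.10, adjusted p = 0.0581) came from the centring, since uncentred it was -0.22. Quantile normalisation kept only miR-126, miR-142-3p and miR-1290 of the 6 and added miR-1260. A variance trend lost miR-150 and miR-520c-3p, and a cutoff of 38 or none lost miR-520c-3p.

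At an unadjusted p under 0.05 there were 15 higher and 25 lower microRNAs, and the groups did not overlap for 21 higher and 61 lower, where chance gives 33.3% of microRNAs in either direction together. The median change of all 100 was -0.71, and 73 had a negative change. The centring sets the mean of the 100 changes to 0. The large positive changes, among them the 10 that the cutoff admitted only as positive, therefore push the others down. Centred on the median, the median change was -0.20. The excess of negative changes and of lower microRNAs without overlap is thus in part set by the centring. The largest negative changes belonged to let-7e (-3.41, SE 0.88, adjusted p = 0.0781) and let-7b (-3.29, SE 1.07, adjusted p = 0.1003), followed by miR-214 (-2.69), miR-328 (-2.43), let-7d (-2.39), miR-331-3p (-2.37), let-7g (-2.20), miR-365 (-2.15), miR-155 (-1.95) and miR-34a (-1.94), none past the threshold. Without microvesicles replicate 1, 16 were lower and without microvesicles replicate 2, 30 were lower. All 10 had positive changes when centred on U6. With the replicate number as a block, 12 microRNAs were lower, though the labels do not show that samples of the same number are paired. miR-31 (-1.28, SE 0.37, adjusted p = 0.0931), miR-21 (-0.64, SE 0.57) and miR-16 (-1.28, SE 0.39) did not pass.

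**Figure D2:**
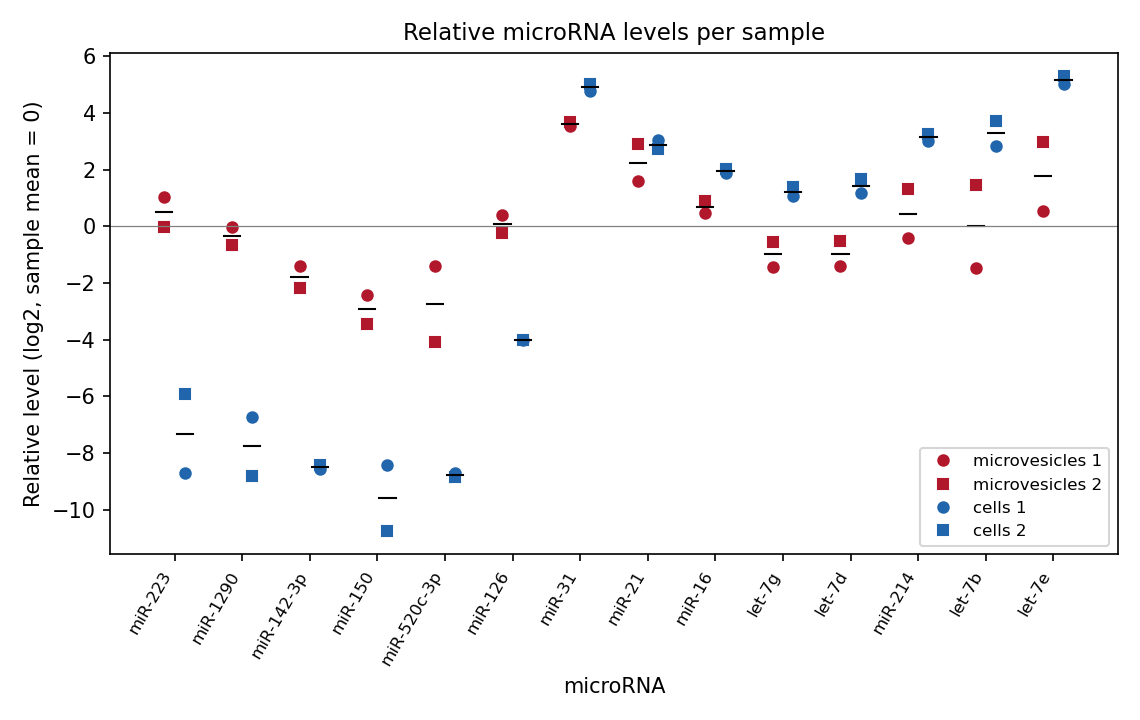
Relative level (y axis, log2, mean of the 100 common microRNAs at 0) of 14 microRNAs in each sample, with circles for replicate 1, squares for replicate 2 and bars for the mean of each group (n = 2). For miR-126 the microvesicle samples lie near 0 and the cell samples near -4.01, while for let-7e the order is the opposite.

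Of the 9 lists tested, 1 passed, the blood cell list. Its 3 tested members, miR-223, miR-142-3p and miR-150, were higher, with a mean change of 7.07 (camera, adjusted p = 0.000355; adjusted p = 0.450 with an estimated correlation). Their mean cell Ct of 31.4, 32.6 and 33.7 lay later than 29.1, so that the cutoff admitted them to the test only with a positive change and their direction in it is not a separate finding. All 3 passed adjusted over all microRNAs and adjusted over the list alone. Another member, miR-451 of red blood cells, was the 1 microRNA detected in both microvesicle samples (Ct 32.8 and 29.0) and in neither cell sample. It was at least 1087-fold higher relative to the sample means (10.1 on the log2 scale, from 8.95 without cells replicate 2 to 11.2 without cells replicate 1). Of this 10.1, 5.94 was added by the centring, and the bound takes the listed 40 of both cell samples as little template. miR-486-5p was listed at 40 in microvesicles 1 and cells 1, and at 31.0 and 30.1 in the others. The remaining members, named after their values were seen, were miR-142-5p, the other arm of the miR-142 hairpin, at 40 in both microvesicle samples and in cells 1 and at 36.001 in cells 2, and miR-144, at 40 in all samples. The endothelial list holds only miR-126 and its minor strand miR-126# (change 4.89, SE 1.10, adjusted p = 0.0680), too few for a list test.

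The let-7 family, microRNAs of differentiated cells, had 5 tested members, all with negative changes (median -2.39, camera adjusted p = 0.0905; adjusted p = 0.823 with an estimated correlation). The list passed in 7 of 18 alternatives, with adjusted p from 0.000113 to 0.823 over the 18. It passed when centred on the median, on U6 or on miR-16, with quantile normalisation, undetected values set to the cutoff or the replicate number as a block, and without microvesicles replicate 1. None passed over all microRNAs and 5 were lower adjusted over the list alone. Of 15 mesenchymal and stromal microRNAs, 10 were tested and 10 had negative changes, such as miR-125b (-1.82), miR-221 (-1.38), miR-100 (-1.23) and miR-222 (-1.03), with 0 past the threshold (camera adjusted p = 0.114). The list was lower with undetected values set to the cutoff (adjusted p = 0.0109) and without microvesicles replicate 2 (0.0433), over a range of 0.0109 to 0.823 in 19 alternatives. The anti-angiogenic list, which shares miR-100, miR-221 and miR-222 with it, gave 8 negative changes of 8, where 73 of all 100 were negative, 0 past the threshold (adjusted p = 0.114), with miR-24 at -0.77. The pro-angiogenic list had 1 positive change, miR-126, and 3 negative, miR-31, miR-21 and miR-27a (-0.12), with a mean of 0.51 and a median of -0.38 that differ in sign (adjusted p = 0.745). Adjusted over the list alone, 1 was higher and 1 lower. With undetected values set to the cutoff this list was lower (adjusted p = 0.0173), and by fry, which tests a list against no change and not against other microRNAs, it was higher (adjusted p = 0.0222), over a range of 0.0173 to 0.987 in 19 alternatives. Its member miR-130a was detected in microvesicles 2 and both cell samples.

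The other lists tested did not pass with camera's preset correlation. The clusters of miR-17 and its relatives had 2 positive and 8 negative changes (adjusted p = 0.813), with miR-19b at -0.93, miR-20a at -0.61, miR-17 at -0.30 and miR-106a at -0.14. The miR-30 family had 1 positive and 2 negative (adjusted p = 0.784; lower by fry, adjusted p = 0.0180, over a range of 0.0180 to 0.987 in 18 alternatives), with miR-30c at -1.05, miR-30b at -0.88 and miR-30a-5p at 0.34. Of 58 microRNAs of the chromosome 14 cluster, 40 were detected in both cell samples, 7 in both microvesicle samples and 16 in cells only. The 7 tested had 3 positive and 4 negative changes (adjusted p = 0.784), with miR-127-3p at -1.26, miR-376c at -0.82 and miR-485-3p at 0.36. Of 140 minor strands, 36 were detected in both cell samples and 4 in both microvesicle samples, with miR-625# at 3.76, miR-31# at -0.54 and miR-34a# at -0.61 (adjusted p = 0.327). Adjusted over the list alone, 2 were higher. The 4 in both microvesicle samples were on card 2. With each card centred separately the mean difference of the list from other microRNAs went from 1.95 to -0.61. With undetected values set to the cutoff the minor strand list was higher (camera, adjusted p = 0.0393, over a range of 0.0393 to 0.823 in 19 alternatives). Of the 36, 19 were detected in cells only. That setting gives a microRNA in neither microvesicle sample a positive change if its cell Ct is later than 29.1. The direction of the list under it is therefore not a finding. The epithelial, striated muscle, neural, liver, gut and pancreas, and pluripotency lists had 0 members in both microvesicle samples, and the chromosome 19 list had 1 of the 45 it matched, miR-520c-3p. The assay miR-520D-3p, written with a capital letter, was not matched and is outside that count.

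In the cells, 88 microRNAs were detected in both samples and in neither microvesicle sample, of which 26 had a lower bound above 1-fold. let-7a (cell Ct 22.4 ± 1.98, SD, n = 2) was at least 103-fold lower in microvesicles relative to the sample means, miR-210, which is induced by hypoxia, at least 40.9-fold, miR-10b at least 26.9-fold, let-7f at least 22.6-fold, miR-149 at least 16.9-fold, miR-339-5p at least 11.6-fold, miR-425 at least 9.22-fold and miR-382 at least 5.12-fold. All 8 were listed at 40 in both microvesicle samples. The folds take a listed 40 as little template, which is not shown. In cells 1 and cells 2, miR-15a read 40 and 25 and miR-22 read 40 and 24.96. The cell replicates lay 2.28 cycles apart over the common microRNAs. These bounds average samples of unequal depth. Without microvesicles replicate 2 they fell to 36.3-fold for let-7a and 1.81-fold for miR-382, with 15 of the 88 above 1-fold, and without microvesicles replicate 1 they rose to 291-fold and 14.5-fold, with 42 above. Leaving out a cell sample gave 31 and 24. The count was 166 without cells replicate 1 and 165 without microvesicles replicate 2.

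Both arms of 5 hairpins were measured in all samples, and 0 changed in balance (limma, lowest adjusted p = 0.240, with 0 at an unadjusted p under 0.05). The minor arm relative to the main arm changed by 1.34 for miR-34a (SE 0.71), 0.80 for miR-126 (SE 0.91) and 0.74 for miR-31 (SE 0.50), and the 3p arm relative to the 5p arm by -1.22 for miR-30a (SE 0.53) and -1.05 for miR-886 (SE 0.65). The arms of miR-34a, miR-126 and miR-31 were on different cards, and with each card centred separately all 3 had the opposite sign and passed the threshold (adjusted p = 0.0385, 0.0129 and 0.0129). Without microvesicles replicate 1 the second arm was higher in 3 and lower in 2 of 18 hairpins, and without microvesicles replicate 2 it was higher in 2 of 5, miR-126 and miR-34a (adjusted p = 0.0194 each). Over all alternatives the adjusted p of these 3 hairpins ran from 0.0129 to 0.753.

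The reference RNAs did not follow the microRNAs. U6, a spliceosomal small nuclear RNA, had a mean Ct of 27.1 in microvesicles 1, 33.1 in microvesicles 2, 18.2 in cells 1 and 16.9 in cells 2. Relative to the microRNA mean it stood at 4.50 cycles in microvesicles 1 and at -4.53 in microvesicles 2, where a positive value means an earlier Ct, so the microvesicle replicates differed by 9.03 cycles, against 0.97 between the cell replicates. The mean was -0.01 ± 6.39 in microvesicles and 6.59 ± 0.69 in cells (SD, n = 2 each). The nucleolar RNA RNU44 was listed at 40 in both microvesicle samples on card 1 and at 21.5 and 18.9 in cells, but on card 2 at 8.74 in microvesicles 1 and 40 in microvesicles 2. RNU48 was listed at 35.6 and 40 in microvesicles on card 1 and at 40 in both on card 2, against 20.8 to 22.4 in cells. The plant control was listed at 40 in all samples.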

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

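All tests in this part were chosen after the results were seen. Among values that entered no comparison, 5 microvesicle readings had a Ct under 15, earlier than any reading of the microRNAs that were tested apart from miR-1262, in assays with a later Ct or 40 in at least 1 cell sample. RNU44 on card 2 read 8.74 in microvesicles 1 and 40 in microvesicles 2. miR-141# read 9.44 in microvesicles 2 and 40 in the other samples. miR-519b-3p read 14.99 in microvesicles 1 and 40 in the others. miR-549 read 13.0 in microvesicles 1 and 12.1 in microvesicles 2, against 12.4 and 40 in cells.

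U6 was higher in microvesicles 1 than in microvesicles 2 although microRNAs were lower there. Failure of a card or well would leave the other card without the difference, but U6 differed by 6.01 cycles on card 2, over 4 wells, and by 6.05 on card 1, where the wells hold 1 repeated value. Carry-over of whole cellular RNA into microvesicles 1 would bring RNU44 and RNU48 at the distance from U6 seen in cells, yet each lay at least 2.52 cycles later than the later of both cell samples predicts, with values of 40 taken as 35 and the card 2 reading of RNU44 left out. Another source of U6 stays open, and no biological explanation was tested, since both samples belong to the same group.

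Ct values lay close to whole cycles. Within 0.1 cycles of a whole number were 67.4%, 48.8%, 50.0% and 40.6% of the microRNA values below 40 in microvesicles 1, microvesicles 2, cells 1 and cells 2, where an even spread gives 20%, and none was exactly whole. Noise crossing the threshold in late cycles would be confined to late values, and values from 32 to 40 had 67.8%, but cell values from 15 to 24 had 30.6% (exact 95% interval 22.7 to 39.6%), which argues against late noise as the whole source. No biological explanation was tested.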

How the results depend on the processing

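The alternatives with each card centred separately, Ct rounded up and assays under a Ct of 15 left out were chosen after seeing the data. In all, 20 alternatives were run; of 1003 values of single microRNAs, lists and hairpins under them, 116 changed sign, 0 of them past the threshold in both settings and 8 past it in the alternative. These 8 were the pro-angiogenic list with undetected values at the cutoff, the arms of miR-126, miR-31 and miR-34a by card, and miR-1274A, miR-1274B, miR-30a-5p and miR-485-3p uncentred. By construction, U6 centring adds the group difference of relative U6, 6.60 cycles, to every change; other causes were not tested. Depth limits the test to 100 microRNAs, fewer at stricter cutoffs.

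Higher and lower microRNAs numbered 6 and 0. They were 0 and 85 uncentred, 0 and 0 centred on U6, 14 and 0 centred on miR-16, 4 and 1 with quantile normalisation, 2 and 0 of 50 at a cutoff of 32, 5 and 1 at 38 or no cutoff, 0 and 0 with undetected values set to the cutoff, 4 and 3 with a variance trend, 6 and 4 with each card centred separately, 10 and 0 with Ct rounded up and 9 and 0 centred on the median. Leaving out 1 sample gave 0 to 18 higher and 0 to 30 lower, with the lone sample assumed to vary like the other group. The median change of all was -0.71, and -6.65 uncentred, -0.20 with the median, 5.89 with U6, -0.07 with quantile normalisation, 0.59 with miR-16 and -0.43 by card. The replicate block gave 16 higher, 12 lower and 1 list lower; the labels give the replicates only a shared number, and a correlation of 0.199 between deviations of same-numbered samples across microRNAs (0.157 without the assay under a Ct of 15) does not settle in 2 pairs whether they are paired.

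Of the lists, 1 was higher and 0 lower. Higher were 0 at a cutoff of 32, where the blood cell list could not be tested, 0 with an estimated correlation, 2 with undetected values at the cutoff and 2 with fry, which tests a list against no change and not against other microRNAs. For the minor strands, higher with undetected values at the cutoff is not a finding, because that setting makes undetected microRNAs that are late in cells positive. Lower were 1 each with the median, U6, quantile normalisation, miR-16 and fry, 3 with undetected values at the cutoff, and 0 to 1 leaving out 1 sample. The blood cell list passed in 17 of 18 alternatives, fry among them, adjusted p 1.13e-07 to 0.450, which says nothing about its direction where the cutoff of 35 applies, since the cutoff set it. The let-7 list was negative in all 18 and passed in 7, adjusted p 0.000113 to 0.823: with the median, U6, quantile normalisation, miR-16, undetected values at the cutoff, the replicate block and without microvesicles replicate 1. The mesenchymal and stromal list was lower with undetected values at the cutoff (adjusted p = 0.0109) and without microvesicles replicate 2 (0.0433), of 19 alternatives ranging up to 0.823. Detected microRNAs were 53 and 128 in microvesicles at a cutoff of 32. Only in microvesicles were 0 at a cutoff of 32 and 2 to 7 leaving out 1 sample, and only in cells 89 to 166. Hairpins with a changed balance were 3 lower with each card centred separately, and 0 to 3 higher and 0 to 2 lower leaving out 1 sample.

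Values that changed sign follow; for a list, the value is the mean difference from other microRNAs and the sign that of the test. Uncentred, miR-126 was -1.84, miR-126# -1.05, miR-1262 -0.22, miR-1274A -4.28, miR-1274B -4.82, miR-1267 -4.03, miR-30a-5p -5.60, miR-485-3p -5.58, miR-625# -2.18 and the chromosome 14 list -0.0054, as with fry. Centred on U6, let-7e was 3.20, let-7b 3.32, miR-214 3.92, miR-328 4.18, let-7d 4.21, miR-331-3p 4.24, let-7g 4.40, miR-365 4.45, miR-155 4.65, miR-34a 4.66, miR-222 5.57, miR-99a 5.41, miR-100 5.38, miR-720 6.36, miR-17 6.31, miR-31 5.32, miR-221 5.23, miR-24 5.83, miR-19b 5.67, miR-21 5.96, miR-27a 6.49, miR-125b 4.79, miR-106a 6.46, miR-20a 5.999, miR-30c 5.55, miR-30b 5.72, miR-127-3p 5.34, miR-376c 5.79, miR-31# 6.06, miR-34a# 5.998 and miR-16 5.32. Centred on miR-16, miR-222 was 0.25, miR-99a 0.090, miR-100 0.052, miR-720 1.04, miR-17 0.98, miR-24 0.51, miR-19b 0.35, miR-21 0.64, miR-27a 1.16, miR-106a 1.14, miR-20a 0.68, miR-30c 0.23, miR-30b 0.40, miR-127-3p 0.017, miR-376c 0.46, miR-31# 0.74, miR-34a# 0.67, the miR-17 cluster list -0.66 and the miR-30 list -0.56. With quantile normalisation, miR-1262 was 0, miR-720 0.61, miR-17 0.29, miR-21 0.13, miR-27a 0.68, miR-106a 0.43, miR-20a 0.24, miR-30b 0.33, miR-31# 0.44, miR-34a# 0.045, the miR-17 cluster list -0.16, the miR-30 list 0.33 and the chromosome 14 list -0.090. With the median, miR-720 was 0.26, miR-17 0.21, miR-27a 0.39, miR-106a 0.36 and the miR-17 cluster list -0.65. At a cutoff of 32, miR-27a was 0.044, miR-106a 0.015 and the miR-17 cluster list -0.23. At 38 or no cutoff they were 0.069, 0.040 and -0.43. With each card centred separately, miR-1274A was -0.80, miR-1274B -1.34, miR-1267 -0.55, miR-17 0.21, miR-27a 0.39, miR-106a 0.36, miR-30a-5p -2.13, the arms of miR-126 -2.17, of miR-31 -2.22 and of miR-34a -1.63, the minor strand list -0.61 and the miR-17 cluster list -0.089. With Ct rounded up, miR-720, miR-17, miR-27a and miR-106a were 0.38 and miR-485-3p -0.12. With undetected values at the cutoff the pro-angiogenic list was -2.38. Over the samples left out in turn, the pro-angiogenic list ran from -0.21 to 0.49, the miR-17 cluster list from -1.14 to -0.097, the chromosome 14 list from -0.25 to 0.36, the arms of miR-126 from -0.44 to 2.04, miR-720 from -1.37 to 1.03, miR-21 from -1.36 to 0.23, miR-27a from -0.31 to 0.046, miR-106a from -0.33 to 0.089, miR-20a from -1.12 to 0.065 and miR-485-3p from -0.086 to 0.95.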

Other observations

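Some assays in the panel match fragments of other small RNAs, and these were picked after their values were seen. miR-1274A, miR-1274B, miR-720 and miR-1260, whose sequences are now assigned to transfer RNA, were detected in all samples. Relative to the microRNA mean, miR-1260 changed by 1.74 (SE 0.42, limma adjusted p = 0.0741), miR-1274A by 1.66 (SE 0.48, adjusted p = 0.0931), miR-1274B by 1.12 (SE 0.45) and miR-720 by -0.24 (SE 0.79). All 4 were on card 2, and with each card centred separately they stood at -0.72, -0.80, -1.34 and -2.71. miR-886-3p and miR-886-5p, picked along with them, changed by -0.60 (SE 0.55) and 0.45 (SE 0.54). miR-144, whose gene lies beside that of miR-451 in assembly GRCh38.p14, was listed at 40 in all samples.

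All tests from here on were chosen after the results were seen. Detection in both microvesicle samples, among microRNAs found in both cell samples and compared within bins of 2 cycles of cell Ct, passed after adjustment over 4 lists for none of them: the pro-angiogenic list (4 of 12, odds ratio 0.18, exact p = 0.0306, adjusted p = 0.122), the chromosome 14 cluster (7 of 40, odds ratio 0.48, adjusted p = 0.340), minor strands (4 of 36, 0.44, adjusted p = 0.369) and the let-7 family (5 of 7, 0.63, adjusted p = 0.632).

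Among microRNAs detected in both cell samples, 11 of 114 with a mean cell Ct of 28 to 35 were in both microvesicle samples, and those tested later than 29.1 were relatively higher as the cutoff requires; miR-142-3p, miR-223, miR-150 and miR-451 were in both microvesicle samples. A signal that does not follow template would give replicates of unequal RNA the same Ct. That RNA was unequal is assumed from the microRNA Ct values, and U6 ran the other way in microvesicles (27.1 and 33.1). Replicates differed by 3.10 cycles for miR-142-3p, miR-223 and miR-451 (SE 0.59, 5 differences) and by 2.33 for miR-126 (SE 0.046, 2 differences), near the 2.64 of all tested microRNAs. The mean of 3.10 covers 5.08 in cells and 1.94 in microvesicles for miR-223 and 1 difference for miR-451. All these differences come from the same 2 pairs of samples and are not independent, so the SEs and intervals are only descriptive. These microRNAs moved in the direction of the others, which does not settle the question for them. A signal that does not follow template stays most open for miR-150, at -0.06 in cells and 1.99 in microvesicles (mean 0.97, SE 1.02). miR-150 was set apart from the others (2.49 for all 4, SE 0.61) once its values were seen. The same holds for miR-1290 and miR-520c-3p (1.26, SE 0.57, 4 differences). For these the 95% t intervals, a rule set after a first look with 2 standard errors, hold both 0 and 2.64. Selection of late assays by the cutoff stays open for all of these microRNAs that are late in cells, and for miR-126 at a mean cell Ct of 28.1. Among microRNAs with a mean cell Ct of at least 30 and detected in both cell samples, 3 of 3 blood list members (miR-142-3p, miR-223 and miR-150) were in both microvesicle samples, against 5 of 73 others (two-sided Fisher exact p = 0.000797, adjusted p = 0.00637 over 8 lists). The list was fixed before the data were examined, but the test was chosen once these 3 were known to be in all samples. It restates that observation and cannot weigh against selection, and it has no bearing on direction. The other list members were not detected in both cell samples and took no part. For miR-1290 and miR-520c-3p, independent detection gives 1.48 of the 73 in both and 5 were (Fisher exact p = 0.00288 for the 5 together). miR-451 was the 1 of 392 in neither cell sample that both microvesicle samples held, where 0.0536 is expected (Fisher exact p = 0.0528). RNA of serum in the conditioning medium cannot be told apart from loading into vesicles, a biological explanation not tested. The labels of the cell samples name no such conditioning, so a difference in culture cannot be told apart either. The 7 serum and blood microRNAs examined include the 4 that raised the question. That 4 of 7 were in both microvesicle samples was thus known beforehand and decides nothing. Of the others, miR-122 and miR-144 were listed at 40. miR-486-5p stood at 40 in microvesicles 1 and at 31.0 in microvesicles 2, against 40 and 30.1 in cells. No medium without cells was analysed here.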
